A study of Methylotuvimicrobium buryatense with 8 samples.

How the data were processed

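RNA was sequenced from *Methylotuvimicrobium buryatense* 5GB1C, a bacterium that grows on methane. Cultures of the wild type and of a lanA mutant were grown under methane and air with 0 or 30 µM lanthanum and harvested in exponential phase, per the labels' protocols. The labels give 4 groups of 2 libraries each and call the 2 libraries of a group biological replicates. RNA was purified with DNase treatment and sequenced as paired Illumina HiSeq reads of 150 bases, per the labels' protocols. Whether ribosomal RNA was depleted before sequencing is not given in the sources used here.

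Each library came as 1 table of whole-number counts per locus tag, deposited by the authors without normalization. The submitters' processing notes name BWA 0.7.12-r1044, SAMtools, HTSeq, DESeq2 1.2.10 and R 3.3.0, and the layout of the tables, with closing summary lines, is that of HTSeq. The genome build, the version and counting mode of HTSeq and the use of strand are not given in the sources used here. Counts of tags that overlap, or that lie opposite each other on the 2 strands, could therefore not be separated. No record was set aside for a position that was not unique, so any reads shared by near-identical copies lie in the counts or in the class of low alignment quality.

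The 5 summary lines of each table name no tag and stayed out of library totals and tests. Records outside any counted feature made up 5.47% to 9.02% of a library, and records that did not align made up 0.444% to 1.84%. Records of low alignment quality made up 4.55% to 8.88% in 6 libraries, 28.7% in lanA mutant replicate 2 without lanthanum and 43.8% in lanA mutant replicate 1 with lanthanum. Between 13619010 and 27081075 records per library were counted to tags. At this depth 3 counts correspond to 0.110 to 0.219 counts per 1000000 (CPM), a floor that covers counting error only.

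The tables hold 4427 locus tags and do not pair them with gene names, and no annotation was used here. Tags are therefore given as the tables write them, no gene name was assigned to any tag, and no level is given for lanA itself. The 25 gene lists planned for this organism, among them methanol dehydrogenase and methane monooxygenase genes, and their set tests could not be run. Tags for ribosomal or transfer RNA, if counted, stayed in the library totals.

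Counts were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Tags were filtered with filterByExpr at its defaults, a minimum count of 10 and a minimum total of 15, which left 4375 tags and removed 52. Libraries were scaled by TMM. A quasi-likelihood model with robust dispersion and 1 mean per group was fitted to all 8 libraries, which leaves 4 residual degrees of freedom, and the common dispersion was 0.0211. F-tests were made for 5 comparisons: lanthanum in the wild type, lanthanum in the mutant, mutant against wild type without and with lanthanum, and the difference of the lanthanum responses. Tags with a Benjamini-Hochberg adjusted p under 0.05 over the 4375 tags passed the test. Log2 fold changes are given with standard errors derived from the F statistic and, where stated, 95% confidence intervals. Levels are TMM-scaled CPM, as mean ± SD of 2 libraries.

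Groups, tests, alternatives and the rule for naming tags were fixed before the data were examined. The rule took, per comparison, the tags with the largest change in each direction among those that passed, with a mean of at least 10 CPM in the higher group and no overlap between the replicates of the groups compared (overlap was not considered for the difference of responses). Because no annotation was used, at most 2 tags per direction are named. Runs of consecutive tags, meaning tags whose numbers follow each other in the steps of 5 used by the tables, were described after the results had been seen.

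The alternatives were the DESeq2 1.42.0 Wald test, RLE size factors, library totals without TMM, no filter beyond 1 count in all, the replicate number as a block, only the groups compared, each library left out in turn, the 10 most abundant tags left out, and a minimum absolute log2 fold change of 1. After the data had been seen, 2 more were added: both libraries rich in low-quality records left out, and all libraries thinned to the smallest total.

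The procedure was tested on simulated counts for the 4375 tags with 200 changed tags. Each tag was drawn independently, so shifts shared by many tags of a library were not simulated. In the wild-type lanthanum comparison, edgeR recovered 28.4% of tags changed 1.5-fold, 86.6% of those changed 2-fold and 98.5% of those changed 4-fold. In the mutant lanthanum comparison the shares were 35.8%, 91.0% and 98.5%. For the difference of responses they were 7.46%, 46.3% and 98.5%. Among its simulated calls, 7.79%, 6.83% and 5.61% were unchanged tags in these 3 comparisons, against 14.3%, 13.8% and 15.4% with DESeq2. For mutant against wild type, the shares with edgeR were 10.1% without lanthanum and 3.90% with it, against 17.5% and 11.3% with DESeq2. Replicate libraries were compared by chi-square over tags with at least 20 counts in the pair. The statistic per degree of freedom lay between 15.3 and 182, far above sampling noise, so each library was kept as a replicate.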

Results

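Transcript levels were measured by RNA sequencing in *Methylotuvimicrobium buryatense* 5GB1C, an aerobic methanotroph, to ask how the cells respond to lanthanum and whether that response needs lanA. The series title describes lanA as a TonB-dependent receptor, a kind of outer-membrane protein that imports metals and other scarce nutrients, required for the lanthanide switch. In methanotrophs this switch is the exchange of a calcium-dependent methanol dehydrogenase for a lanthanide-dependent one. Wild-type and lanA mutant cultures were grown with 0 or 30 µM lanthanum, with 2 biological replicates in each of the 4 groups. Counts were obtained for 4427 locus tags, of which 4375 were tested. The tables do not pair tags with gene names, so neither lanA nor the dehydrogenase genes could be pointed out among the tags.

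Counts per library ranged from 13619010 to 27081075. The wild-type libraries held 21261366 and 25235776 counts without lanthanum and 22860233 and 27081075 with it. The mutant libraries held 23101388 and 16100464 counts without lanthanum and 13619010 and 20293718 with it. The 2 shallowest libraries had many records set aside for low alignment quality, 28.7% in mutant replicate 2 without lanthanum and 43.8% in mutant replicate 1 with lanthanum, against 4.55% to 8.88% in the other libraries. The 10 most abundant tags took 35.3% to 41.5% of the counts. Across tags, log2 CPM of the replicates correlated with Pearson's r of 0.979 in the wild type without lanthanum, 0.993 in the wild type with lanthanum, 0.982 in the mutant without lanthanum and 0.996 in the mutant with lanthanum.

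**Figure D1:**
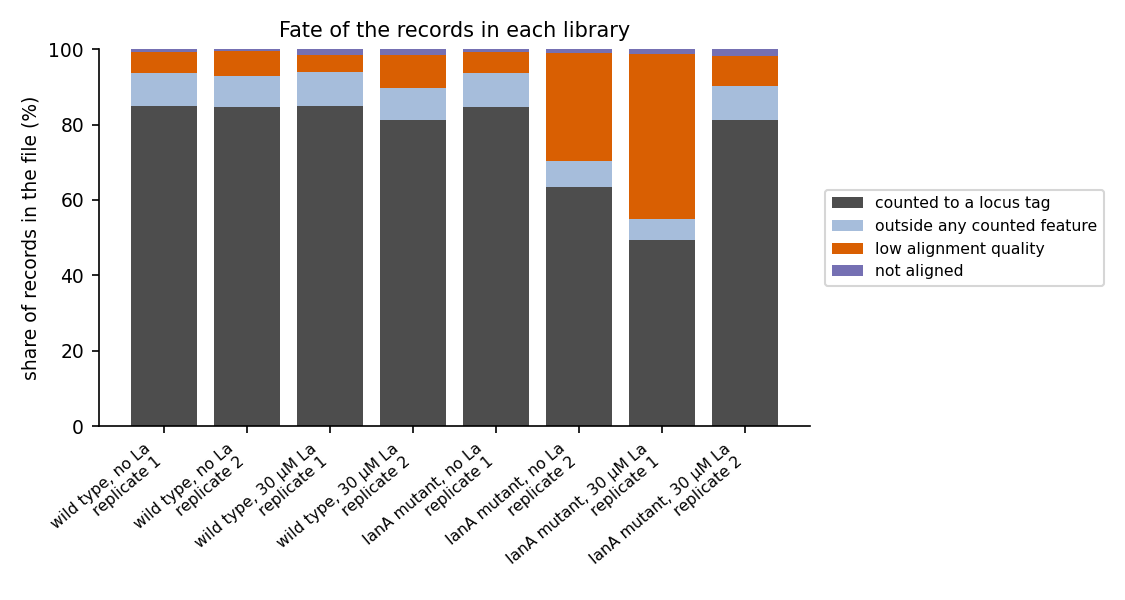
Share of records in each of the 8 libraries (vertical axis, %) that were counted to a locus tag, lay outside any counted feature, had low alignment quality or did not align, as stacked bars. Low alignment quality took 28.7% and 43.8% of the records in 2 mutant libraries and at most 8.88% in the others.

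In the wild type, lanthanum lowered a block of tags, some of them highly expressed, to a small fraction of their level. EQU24_18145 stood at 49802 ± 8711 counts per 1000000 (CPM; SD, n = 2) without lanthanum and at 41.1 ± 0.621 CPM with it, a 1211-fold fall. The adjoining EQU24_18140 fell 947-fold, from 8883 ± 899 to 9.37 ± 0.169 CPM. In the other direction, EQU24_18605 rose 9.61-fold, from 1598 ± 175 to 15355 ± 2465 CPM, and EQU24_19210 rose 3.24-fold, from 53.9 ± 12.9 to 175 ± 4.76 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold changes were -10.24 (SE 0.23, adjusted p = 4.12e-07) for EQU24_18145 and -9.89 (SE 0.21, adjusted p = 4.12e-07) for EQU24_18140. In the same edgeR test, they were 3.26 (SE 0.19, adjusted p = 7.53e-05) for EQU24_18605 and 1.70 (SE 0.17, adjusted p = 0.00301) for EQU24_19210.

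In all, 23 of the 4375 tags passed the test for lanthanum in the wild type, 3 higher and 20 lower, and 22 of them (3 higher, 19 lower) changed by more than 1 on the log2 scale. At an unadjusted p under 0.05 there were 287 tags, where chance gives 219. DESeq2 called 49 tags (18 higher, 31 lower), and edgeR called 35 without wild-type replicate 1 grown without lanthanum; both sets held all 23. EQU24_19210 no longer passed when only the groups compared were fitted (edgeR adjusted p = 0.0601) or when both libraries rich in low-quality records were left out (edgeR adjusted p = 0.0547); its adjusted p over the alternatives ranged from 1.59e-15 to 0.0601.

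The fall was concentrated in 2 runs of consecutive tags. A run of 14 tags, which holds EQU24_18140 and EQU24_18145, fell throughout, by up to 1211-fold, with log2 fold changes from -10.24 to -4.00 and a median of -6.49. Together these 14 tags took 7.60% ± 0.820 (SD, n = 2) of the counts without lanthanum and 0.0180% ± 0.000748 with it. A second run of 5 tags, at 22.4 to 111 CPM in the wild-type libraries without lanthanum, fell by 2.28-fold to 5.58-fold. Its share went from 0.0257% to 0.00634% of the counts. The tags on either side of the runs did not pass the test. Beside the run of 14 the log2 fold changes were 0.23 (edgeR adjusted p = 0.815) and -0.06 (edgeR adjusted p = 0.932), and beside the run of 5 they were -0.56 (edgeR adjusted p = 0.745) and 0.30 (edgeR adjusted p = 0.802). Of the 4 tags outside the runs that passed, 3 rose, by 1.04 to 3.26 on the log2 scale, and 1 fell by 0.84. The 23 tags formed 17 adjacent pairs, against at most 4 in 99999 random draws of 23 tested tags (permutation p = 1e-05, one-sided, the smallest these draws can give). The runs were chosen after the result was seen, and the test describes clustering only.

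**Figure D2:**
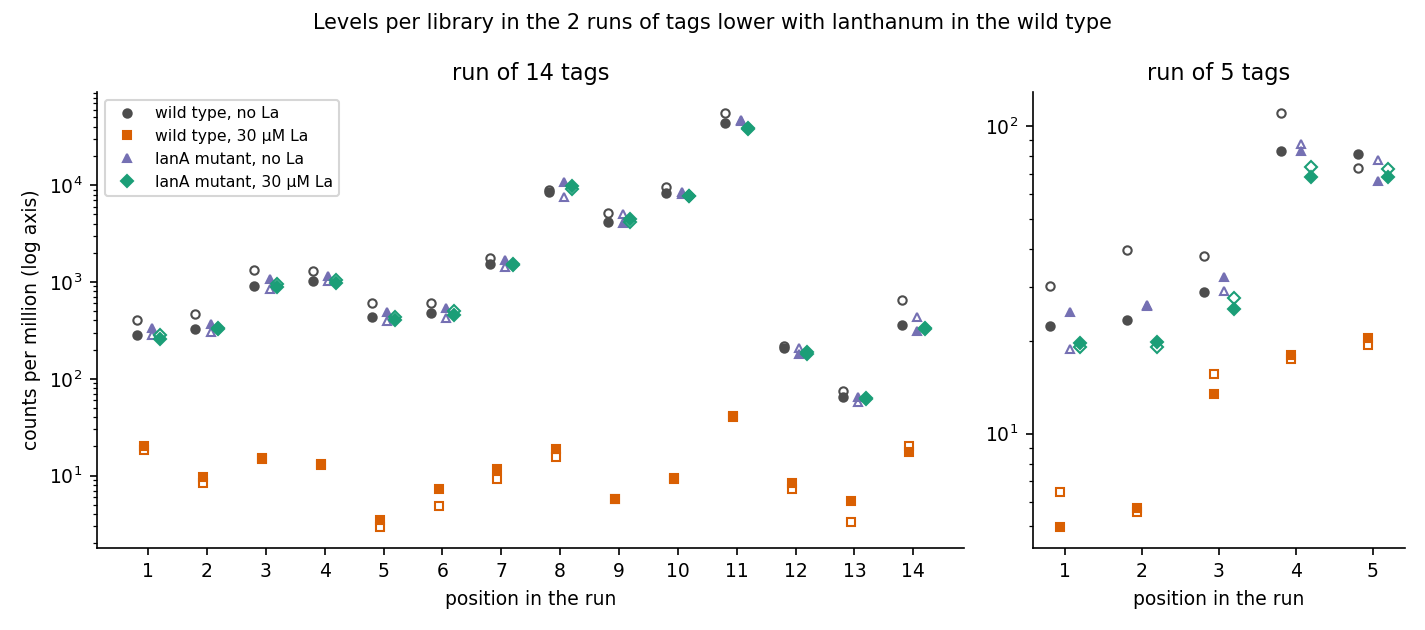
Levels in CPM (vertical log axis) of the tags in the run of 14 and the run of 5 consecutive tags that fell with lanthanum in the wild type, by position in the run (horizontal axis). Filled symbols are replicate 1 and open symbols replicate 2 of the 4 groups; the wild type with lanthanum lies below the other 3 groups at every position, while both mutant groups lie near the wild type without lanthanum.

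In the lanA mutant given lanthanum, the same tags changed less. Among the tags named above, EQU24_19210 changed most, with a 1.42-fold rise that did not pass the test. EQU24_18145 was at 46221 ± 1087 CPM (SD, n = 2) without lanthanum and 38530 ± 880 CPM with it, and EQU24_18140 at 8342 ± 330 and 7749 ± 73.2 CPM. EQU24_18605 was at 1330 ± 1.81 and 1454 ± 148 CPM, and EQU24_19210 at 49.1 ± 5.81 and 69.7 ± 3.92 CPM. The run of 14 tags took 7.60% ± 0.148 of the counts without lanthanum and 6.62% ± 0.0616 with it. Its log2 fold changes lay between -0.26 and 0.04, and all their 95% confidence intervals lay within -0.81 to 0.50. Those of the run of 5 lay between -0.42 and -0.03, with intervals within -0.95 to 0.32.

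No tag passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment for lanthanum in the mutant; the smallest adjusted p was 0.299. At an unadjusted p under 0.05 there were 571 tags, where chance gives 219. DESeq2 called 133 (124 higher, 9 lower), none of which was among the 23 tags called in the wild type. It gave no adjusted p for 1612 of the 4375 tags here, and these count as not called. The log2 fold changes and 95% confidence intervals were -0.26 (-0.62 to 0.09, edgeR adjusted p = 0.493) for EQU24_18145 and -0.11 (-0.43 to 0.22, edgeR adjusted p = 0.740) for EQU24_18140. They were 0.13 (-0.27 to 0.53, edgeR adjusted p = 0.748) for EQU24_18605 and 0.51 (0.11 to 0.90, edgeR adjusted p = 0.299) for EQU24_19210. Both libraries rich in low-quality records are mutant libraries, 1 in each of the groups compared here. With the replicate number as a block, edgeR called 339 tags (316 higher, 23 lower), none of them among those called in the wild type. The labels do not say that the replicate numbers pair the cultures.

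The difference of the lanthanum responses was tested in its own contrast. For 17 tags the response of the mutant differed from that of the wild type, all by more than 1 on the log2 scale; for 16 the log2 fold change was higher in the mutant, where it lay near 0, and for 1, EQU24_18605, it was lower. All 14 tags of the long run were among them, with differences of 3.99 to 9.98, as were 2 of the 5 tags of the short run. All 17 also belong to the 23 tags called in the wild type, and the other 6 of those 23 did not pass. EQU24_18145 differed by 9.98 (SE 0.26, edgeR adjusted p = 1.23e-06), EQU24_18140 by 9.78 (SE 0.23, edgeR adjusted p = 1.23e-06) and EQU24_18605 by -3.14 (SE 0.25, edgeR adjusted p = 0.000796). EQU24_19210 differed by -1.19, which did not pass (edgeR adjusted p = 0.265), though it did with DESeq2 (adjusted p = 0.00445) and with edgeR without wild-type replicate 1 grown without lanthanum (adjusted p = 0.0302); its adjusted p over the alternatives ranged from 0.00445 to 1.00. DESeq2 called 27 tags for the difference (23 higher, 4 lower) and gave no adjusted p for 255. Without the 2 libraries rich in low-quality records, 12 of the 14 tags of the long run passed for the difference, and EQU24_18605 no longer did, at -3.24 (edgeR adjusted p = 0.109); its adjusted p over the alternatives ranged from 3.71e-36 to 0.109.

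Across the 23 tags called in the wild type, the median absolute log2 fold change was 4.73 in the wild type and 0.12 in the mutant, and the largest in the mutant was 0.51. For 21 of the 23 tags the sign was the same in both strains. Most of these lie in the 2 runs, where 12 of 14 and 5 of 5 tags were below 0 in the mutant. Neighbouring tags may share transcripts, so the signs are not independent, and none of the 23 passed in the mutant.

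**Figure D3:**
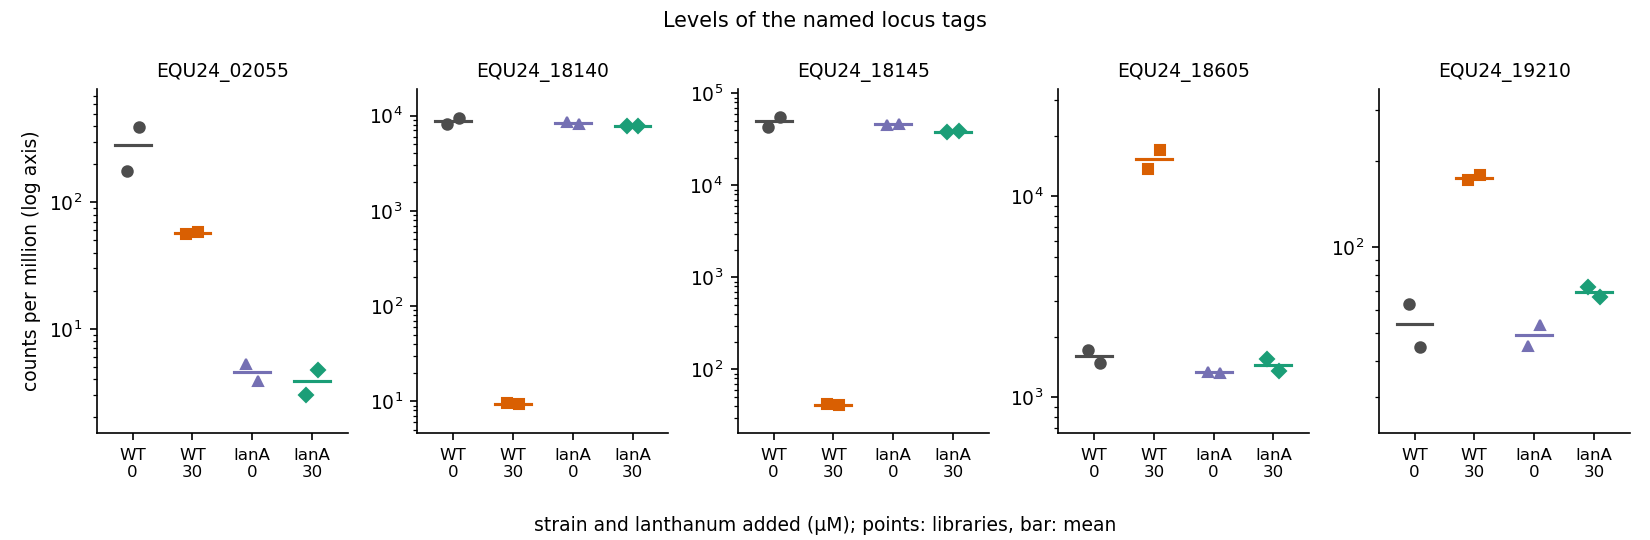
Levels of 5 locus tags in CPM (vertical log axes with a different range in each panel) in the wild type (WT) and the lanA mutant with 0 or 30 µM lanthanum; points are libraries and bars are means of 2. EQU24_18145 and EQU24_18140 drop to 41.1 and 9.37 CPM only in the wild type with lanthanum, EQU24_18605 reaches 15355 CPM only there, and EQU24_02055 lies at 4.56 and 3.84 CPM in the mutant groups.

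Without lanthanum the strains differed in 1 tag. EQU24_02055 was at 286 ± 153 CPM (SD, n = 2) in the wild type, with 178.0 and 394 CPM in its libraries, and at 4.56 ± 1.03 CPM in the mutant, 62.0-fold lower. The tags that responded to lanthanum in the wild type were at similar levels in the cultures of both strains grown without it. The run of 14 tags took 7.60% of the counts in each, with log2 fold changes between -0.44 and 0.09 and 95% confidence intervals within -1.07 to 0.55. EQU24_18605 differed by -0.26 and EQU24_19210 by -0.13 on the log2 scale (edgeR adjusted p = 0.919 for both).

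The log2 fold change of EQU24_02055 was -5.95 (SE 0.45, adjusted p = 0.00991, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). DESeq2 also called 1 tag, and 123 tags had an unadjusted p under 0.05 in edgeR, fewer than the 219 that chance gives. The call ended when only the groups compared were fitted (edgeR adjusted p = 0.246), without mutant replicate 1 (0.296) or 2 (0.390) grown without lanthanum, and without both libraries rich in low-quality records (0.803). The log2 fold change stayed between -6.40 and -5.27 over the alternatives, while its adjusted p ranged from 4.17e-55 to 0.803. In each of the 4 mutant libraries the tag lay at or under 5.29 CPM, and in each of the 4 wild-type libraries at or above 56.1 CPM (exact permutation p = 0.0286, two-sided, the smallest that 70 splits allow; the tag was chosen from the same libraries).

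With lanthanum the strains stood far apart. All 14 tags of the long run were higher in the mutant, by 14.2-fold to 937-fold, and took 6.62% ± 0.0616 (SD, n = 2) of its counts against 0.0180% ± 0.000748 in the wild type. EQU24_18145 was 937-fold and EQU24_18140 826-fold higher in the mutant. EQU24_18605 was 10.6-fold lower, at 1454 ± 148 CPM against 15355 ± 2465 CPM. EQU24_02055 was 14.6-fold lower, at 3.84 ± 1.19 CPM against 57.3 ± 1.72 CPM. Of the run of 5 tags, 4 passed as higher in the mutant, and the remaining 1 had a log2 fold change of 0.87 (edgeR adjusted p = 0.108).

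In this comparison 23 tags passed edgeR's test with Benjamini-Hochberg adjustment, 18 higher and 5 lower in the mutant, and 22 (18 higher, 4 lower) changed by more than 1 on the log2 scale. The log2 fold changes were 9.87 (SE 0.22, edgeR adjusted p = 4.89e-07) for EQU24_18145, 9.69 (SE 0.20, edgeR adjusted p = 4.89e-07) for EQU24_18140, -3.40 (SE 0.19, edgeR adjusted p = 6.28e-05) for EQU24_18605 and -3.87 (SE 0.43, edgeR adjusted p = 0.00807) for EQU24_02055. The comparison shares the wild-type libraries with lanthanum with the one that picked the runs, so it is no independent evidence for them. DESeq2 called 290 tags (253 higher, 37 lower), edgeR on only the groups compared called 529 (387 higher, 142 lower), and 723 tags had an unadjusted p under 0.05, where chance gives 219. EQU24_02055 no longer passed without mutant replicate 1 (edgeR adjusted p = 0.127) or 2 (0.0807) grown with lanthanum or without both libraries rich in low-quality records (0.372), with adjusted p over the alternatives from 1.38e-22 to 0.372.

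EQU24_02055 was also lower with lanthanum in the wild type, where its log2 fold change of -2.32 (SE 0.36) did not pass (edgeR adjusted p = 0.0573). It passed with 6 alternatives, among them DESeq2 (adjusted p = 1.09e-08), library totals as the only scaling (edgeR adjusted p = 0.0424) and libraries thinned to the smallest total (0.0422), and without wild-type replicate 1 or 2 grown without lanthanum edgeR gave -2.77 (adjusted p = 0.00137) and -1.64 (adjusted p = 0.0325). Over the alternatives its adjusted p ranged from 1.09e-08 to 0.651. Its response in the mutant differed from that in the wild type by 2.09, which did not pass (edgeR adjusted p = 0.778) except with DESeq2 (adjusted p = 0.0138) and without wild-type replicate 1 grown without lanthanum (edgeR adjusted p = 0.0325), over a range of 0.0138 to 1.00.

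Outside the tags called in the wild type, the 2 lanthanum responses were correlated across tags. Over the 4352 tags not called there, Pearson's r of the log2 fold changes of the wild type and the mutant was 0.555 and Spearman's rho 0.518. Both responses also followed the mean difference of replicate 1 and replicate 2 in the wild type, with r of 0.576 for the wild type and 0.725 for the mutant. The partial r of the 2 responses given that difference was 0.244. That difference is a measure from the same libraries as the wild-type response and was chosen after the data had been seen. Between the 2 responses, r was 0.381 and rho 0.122 over the 23 called tags, and r was 0.314 and rho 0.519 over all 4375 tags. The responses share no library, but tags are not independent replicates and no p is given. The value over all tags leaned on single libraries, with r of 0.0625 without wild-type replicate 2 and 0.504 without wild-type replicate 1, both grown without lanthanum, and 0.132 without wild-type replicate 1 grown with lanthanum. The r of 0.555 and the partial r of 0.244 over the 4352 tags were not computed with libraries left out, so they may lean on single libraries too.

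**Figure D4:**
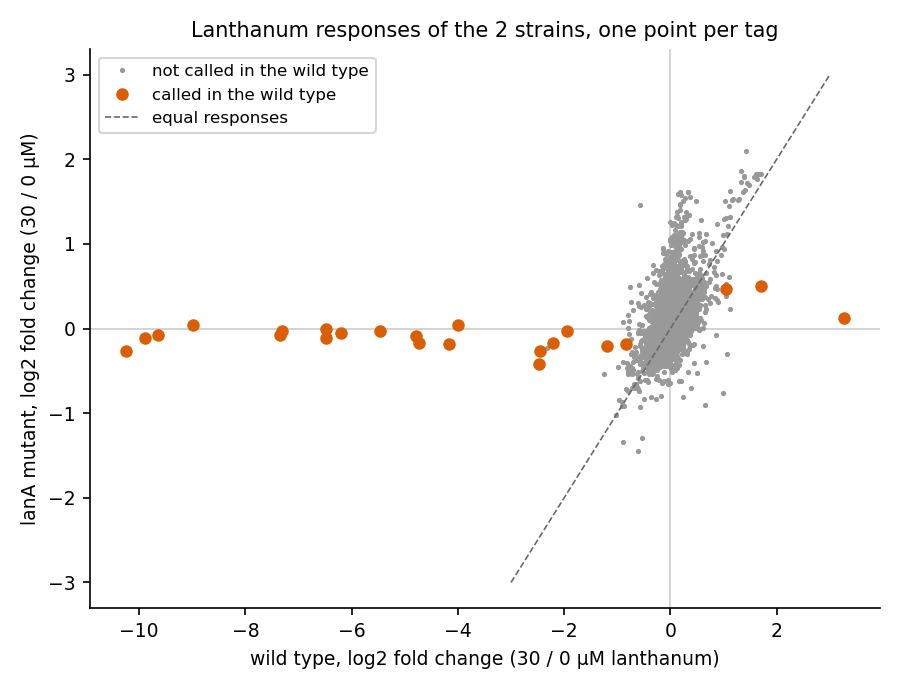
Log2 fold change with lanthanum (30 against 0 µM) in the wild type (horizontal axis) and in the lanA mutant (vertical axis), with 1 point per tag for the 4375 tags tested and the line of equal responses dashed. The 23 tags called in the wild type (larger points) reach from -10.24 to 3.26 there and stay within 0.51 of 0 in the mutant.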

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

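In this part, the tests of exchanged libraries, of mutant cultures without lanthanum, of culture variation and of lower expression of an intact locus were chosen after the results were seen, as was the thinning of libraries to the smallest total. The tests of low alignment quality and of a shared lanthanum effect use the wild-type replicate difference, which was also chosen after the data had been seen. The test of the mutated locus names a tag that the results had singled out.

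The lanthanum response differed between the strains for 17 tags in the test of the difference itself, with log2 differences of 9.98 for EQU24_18145, 9.78 for EQU24_18140 and -3.14 for EQU24_18605 (edgeR adjusted p = 1.23e-06, 1.23e-06 and 0.000796). Lower depth of the mutant libraries does not account for the 0 mutant calls, since 24 tags passed in the wild type after all libraries were thinned to the smallest total. An exchange of 1 mutant with 1 wild-type library grown with lanthanum is argued against by the replicates of these groups, which differed by at most 1.53 on the log2 scale over all tags with at least 10 CPM, where the groups themselves differ by up to 9.87. An exchange of all libraries with lanthanum between the strains is argued against by EQU24_02055, which passed in the libraries without lanthanum as 62.0-fold lower in the mutant and, in the libraries with it, was at most 4.68 CPM in the mutant and at least 56.1 CPM in the wild type; a lost response in the lanA mutant, the biological explanation the design names, stays open as a hypothesis. Mutant cultures that received no lanthanum also stay open, as edgeR called 0 tags between the mutant groups (571 at an unadjusted p under 0.05). DESeq2 called 133, with no adjusted p for 1612 tags, and edgeR with the replicate block called 339 (316 higher, 23 lower). None of these calls was among the tags called in the wild type. Variation between cultures that is not lanthanum could also give such calls, so these counts do not decide it. The share of records that did not align was higher in both mutant libraries with lanthanum (1.25% and 1.84%) than in those without it (0.781% and 0.988%). That does not decide it either.

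In the mutant, 571 tags had an unadjusted p under 0.05 for lanthanum although none passed the adjusted edgeR test and DESeq2 called 133. The mutant log2 fold changes correlated across tags with the mean difference of replicate 1 and replicate 2 in the wild type (Pearson's r = 0.725, Spearman's rho = 0.675), so variation between cultures that is not lanthanum is a candidate explanation. Records of low alignment quality are argued against as the whole cause. The log2 difference between the 2 mutant libraries with few such records still correlated with that replicate difference at r = 0.512. A lanthanum effect that both strains share may also contribute, because the responses kept a partial correlation of 0.244 over 4352 tags given that replicate difference, against 0.555 without it. Both stay open, since that replicate difference comes from the same wild-type libraries as the wild-type response and measures culture variation with error. The partial correlation was not computed with single libraries left out.

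EQU24_02055 was low in every mutant library. Of the tags with at least 10 CPM on average in the wild type, it was the 1 tag whose highest mutant level lay under 25% of its lowest wild-type level. The same libraries had singled it out, so this adds little separate evidence. That it is the mutated locus, lanA, is a hypothesis. Lower expression of an intact locus cannot be excluded, as each mutant library kept at least 41 counts of the tag, up to 122, and no sequence was examined. Of the 20 tags nearest to it, none passed edgeR's test between the strains, although 1 had an unadjusted p under 0.05 without lanthanum and 4 with it. Over all 4375 tags these counts were 123 and 723. The tag that directly follows it was higher in the mutant, by 0.46 without lanthanum and 0.71 with it on the log2 scale (edgeR adjusted p = 0.919 and 0.0715).

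Low alignment quality took 43.8% of the records in mutant replicate 1 with lanthanum and 28.7% in mutant replicate 2 without it, both over 1.5 times the highest wild-type library without lanthanum. By the same measure the share of records that did not align stood out in every library grown with lanthanum, at 1.56% and 1.40% in the wild type and 1.25% and 1.84% in the mutant. With low-quality records left out of the total, these shares were 1.63%, 1.54%, 2.22% and 1.99%, but mutant replicate 2 without lanthanum, at 1.39%, then also exceeded 1.5 times the highest wild-type library without lanthanum (0.757%). With low-quality records kept in the total, the share that did not align was 1.51% ± 0.251 with lanthanum and 0.732% ± 0.225 without it (SD, n = 4 each). The exact permutation p was 0.0286, two-sided, the smallest that 70 splits allow, and its adjusted p was 0.114 over 8 such tests.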

How the results depend on the processing

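Both alternatives without the libraries rich in low-quality records and with thinned libraries, and all alternatives for single tags, were chosen after seeing the data. No named tag that passed changed direction, and 8 of the 13 calls of named tags held under every alternative run for them; EQU24_18145 has no value with the 10 most abundant tags left out, being 1 of them. All tested tags of the run of 14 passed for lanthanum in the wild type under every alternative (12 of 12 when the 10 most abundant tags were left out), and 3 to 5 of the run of 5 did.

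For lanthanum in the wild type, 23 calls became 49 (18 higher, 31 lower) with DESeq2, 50 (24 higher, 26 lower, against 3 and 20) with the replicate block and 20 to 35 with 1 library left out, the 35 without wild-type replicate 1 grown without lanthanum. At least 18 of the 23 remained in each alternative. The block also brought EQU24_02055 past the test there, at -2.24 (edgeR adjusted p = 0.0154). For the mutant, 0 calls became 133 with DESeq2 and 339 (316 higher, 23 lower) with the replicate block, and stayed 0 with any library left out. The fit to only the groups compared leaves fewer residual degrees of freedom and estimates the spread from those groups alone. Across tags, the SD of the log2 difference between replicates was 0.413 in the wild type and 0.396 in the mutant without lanthanum. With lanthanum it was 0.246 and 0.176. For mutant against wild type without lanthanum, EQU24_02055 stood at -5.74 on the log2 scale without the low-quality libraries, and 1 call became 0 with only the groups compared. With 1 library left out it was 0 to 1, the 0 arising without either mutant replicate grown without lanthanum. With lanthanum, 23 calls became 290 with DESeq2, 414 (345 higher, 69 lower) with the replicate block, 529 with only the groups compared and 17 to 28 with 1 library left out. For the difference of responses, 17 calls became 27 with DESeq2, stayed 17 with the replicate block and became 13 (13 higher, 0 lower, all among the 17) without the low-quality libraries, where 12 of the 14 tags of the long run passed. Where the construction of an alternative does not show it, the cause was not tested. A library left without a partner was assumed to vary like the other groups.

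The replicate differences of the 4 groups correlated at 0.0107 to 0.647 over 6 pairs of groups, all above 0. The lowest was between the 2 mutant groups and the highest between the 2 wild-type groups. The labels give no shared day, so whether equal replicate numbers mark cultures grown together cannot be told. The correlation of the responses across all tags ranged from 0.0625 to 0.504 with 1 library left out and was 0.327 with the replicate block. Other scalings moved the median log2 fold change to at most 0.08 from 0. Set tests on gene lists, the genes named in advance and the choice on ribosomal and transfer RNA were not run, as no annotation was used. Simulations recovered few 1.5-fold changes, 28.4% for lanthanum in the wild type and 35.8% in the mutant. Changes of that size may therefore lie below what 2 replicates show. EQU24_19210 in the mutant, for example, ranged from 0.39 to 0.64 on the log2 scale. Larger changes may be missed too, since the simulated tags varied independently, without shifts shared by many tags of a library. In the mutant, 99 tags rose by more than 1 on the log2 scale with lanthanum and 0 passed.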

Other observations

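This part describes a stretch of tags that was chosen after the results were seen, and no planned test bears on it.

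A single stretch of 32 consecutive tested tags had higher mean levels with lanthanum in both strains. It holds all 27 tags whose log2 fold change exceeded 1 in both the wild type and the mutant, among 4375 tested, and 1 tag elsewhere lay under -1 in both. Over the 32 tags the log2 fold change ran from 0.62 to 1.71 in the wild type (median 1.29) and from 0.91 to 2.10 in the mutant (median 1.57). Their summed share of the counts was 0.302% ± 0.196 (SD, n = 2) without and 0.730% ± 0.221 with lanthanum in the wild type, and 0.400% ± 0.240 without and 1.16% ± 0.178 with lanthanum in the mutant. Of the 36 tags above 1 in the wild type, 27 were also above 1 in the mutant, against 99 of all 4375 tags in the mutant. The mutant libraries had no part in picking the 36, but the 27 lie in 1 stretch and are not independent. Over the 4352 tags not called in the wild type, both responses correlated with the wild-type replicate difference (r = 0.576 in the wild type, 0.725 in the mutant). A difference between cultures could therefore also give this overlap.

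None of the 32 passed edgeR's test in either strain (smallest adjusted p = 0.536 in the wild type and 0.299 in the mutant). In edgeR, 16 and 28 of them had an unadjusted p under 0.05, against 287 and 571 of all 4375 tags. DESeq2 called 3 and 7 of them, against 49 and 133 of all tags. The stretch was picked by its changes in both strains, so a raised count of small p follows in part from that choice. With the replicate block, edgeR called 10 of the 32 in the wild type and all 32 in the mutant, against 50 and 339 of all tags. The labels do not say that the replicate numbers pair the cultures. The replicates lay far apart, with replicate 1 above replicate 2 in all 4 groups for 31 of the 32 tags. The summed share was 0.441% and 0.164% in the wild type without lanthanum, 0.886% and 0.574% with it, 0.570% and 0.231% in the mutant without lanthanum, and 1.28% and 1.03% with it. The log2 differences between the responses, 0.05 to 0.66, were all higher in the mutant; none passed (smallest edgeR adjusted p = 1.00), but the simulated test of the difference recovered only 7.46% of 1.5-fold changes, so this does not show equal responses. Neighbouring tags may share transcripts, so the 32 tags are not independent observations. A lanthanum effect that does not need lanA and a difference between cultures both remain candidate explanations; across the 4352 tags not called in the wild type, the partial correlation of the responses was 0.244.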
